A study of Mus musculus with 12 samples.

How the data were processed

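Gene expression was measured by RNA sequencing in mouse splenic B cells grown in the induced germinal centre B cell (iGB) culture, in which naive B cells multiply on feeder cells and some of them switch from IgM to IgG1. Per the labels' protocols, the cells came from wild-type C57BL/6J mice and were left untreated or were given 1 µg/mL of an antibody against the kappa light chain for 12 h. Such an antibody binds surface immunoglobulin of kappa-bearing cells and so engages their B cell receptor (BCR). Live cells carrying CD19 and lacking CD138 were then sorted by flow cytometry into an IgM+ and an IgG1+ fraction. The 12 samples form 4 groups of 3, untreated IgM+, anti-kappa IgM+, untreated IgG1+ and anti-kappa IgG1+. The labels do not say whether the 3 samples of a group came from separate mice or cultures, so p-values measure the spread between these samples only, which may be technical.

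Per the labels' protocols, the libraries were made from polyA RNA with the NEBNext Ultra II RNA kit. STAR, featureCounts and DESeq2 are named without versions in the submitters' processing notes, and the genome build is mm10 (GRCm38). The annotation release and the strand setting of the counting are not given in the sources used here. The deposited count table gives whole-number read counts for 55228 genes in each sample, with each gene's position and exon length, per the file headers. The deposited TPM values (length-scaled shares of the counts) equalled those counts divided by the deposited exon length and rescaled to the same sum in each sample, as a recalculation showed, so they are not an independent measurement. Because the strand setting is not given, a gene that overlaps another on the opposite strand cannot be told apart from it. Genes with related copies, such as the immunoglobulin constant genes, the hemoglobin genes and the class II genes, are uncertain to the extent that the counting could split their reads. Total counts per sample ran from 2119039 to 7705607. Comparing the libraries of each group in pairs, over genes with a combined count of at least 20, gave chi-square values per degree of freedom from 1.86 to 3.91. All pairs therefore differed by more than counting noise, and none was treated as a duplicate.

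The counts were analysed in R 4.3.3 with edgeR 4.0.16. The function filterByExpr, grouped by the 4 groups with a minimum count of 10 and a minimum total count of 15, kept 11875 genes. Library sizes were scaled by TMM, and the robust quasi-likelihood model had 1 term per group over all 12 samples, leaving 8 residual degrees of freedom. All groups entered 1 fit so that they shared an estimate of spread. The 5 comparisons were anti-kappa against untreated in IgM+ cells, the same in IgG1+ cells, IgG1+ against IgM+ in untreated cells, IgG1+ against IgM+ in anti-kappa cells, and the difference of the responses (the IgG1+ response minus the IgM+ response). Benjamini-Hochberg adjustment was over the genes of a comparison, and a gene passed at an adjusted p under 0.05. Levels are CPM after TMM scaling, the count rescaled to the same library size in each sample, as mean ± standard deviation (SD) of 3 samples. Log2 fold changes come from the edgeR model with a standard error (SE), and log2 CPM used a prior count of 2. The isotype check used Python 3.11.15 with SciPy 1.17.1 and exact two-sided permutation tests. Figures were drawn with Matplotlib 3.10.9.

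The samples, comparisons, tests, alternatives, named-gene rule and gene lists were fixed before the data were examined. The named genes were chosen in each comparison by a rule with 3 parts. The first took the 6 passing genes with the largest rise and the 6 with the largest fall, among genes with a mean of at least 5 CPM over the samples compared and with all samples of one group above all samples of the other. For the difference of the responses that last condition was a difference of at least 0.58 on the log2 scale. This part left out immunoglobulin and T cell receptor variable, diversity and joining segments, pseudogenes and unnamed loci. The next part took up to 4 passing genes of smallest p in each list (2 of smallest p where none passed). The last was a fixed set of Ighm, Ighd, Ighg1, Igkc, Nr4a1, Egr1, Egr2, Myc, Irf4, Prdm1, Bcl6, Bach2, Bcl2l11 and Mcl1. Some genes named by the rule were left out of the text for length, and none by its sign. The pattern that left out the segments at first also removed Ighd by mistake, which was corrected after the first list had been seen.

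The 31 gene lists held 631 entries, of which Ctgf, Cyr61 and Ahsp were not found under those names. They covered immediate-early and BCR-induced transcription factors, activation surface markers, NF-kB targets and feedback, ERK feedback, chemokines and cytokines, MYC targets and ribosome biogenesis, glycolysis, cholesterol synthesis, oxidative phosphorylation, the ATF4 integrated stress response, the unfolded protein response and secretion, cell cycle S phase, cell cycle G2 and M phase, pro-apoptotic genes, anti-apoptotic genes, p53 targets, the plasma cell program, mature B cell identity, the germinal centre program, the memory B cell program, proximal BCR signalling, inhibitory BCR regulators, MHC class II and antigen presentation, interferon-stimulated genes, IL-4 and STAT6 targets, integrins, adhesion and migration, and immunoglobulin constant genes. The other lists held markers of fibroblast feeder cells, T and NK cells, myeloid cells, and erythroid cells and platelets. Each list was tested against all other genes with camera (limma 3.58.1) on voom values at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Lists with fewer than 5 tested genes had no set test. List p-values were adjusted over the lists of a comparison. Beside the number of members past the threshold over all genes, the number adjusted over the list alone is given.

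The same replicate numbers occur in every group. After the group means were removed, IgM+ and IgG1+ samples with the same number and the same treatment deviated together across genes, with correlations of at least 0.118 in untreated and at least 0.12 in anti-kappa samples. Between treatments the lowest correlation was 0.0841 in IgM+ and 0.0387 in IgG1+ cells, under the 0.1 needed in every pair. The numbers were therefore taken to pair the isotypes within a treatment, from the data and not from a statement in the labels. They were not used to pair across treatments, although the criterion does not exclude such pairing. Between treatments the highest correlation of different numbers was 0.0284 in IgM+ and 0.00154 in IgG1+ cells, below every pair of the same number. A replicate block over all samples is therefore among the alternatives. A fit with a replicate block within treatment stands beside the isotype counts, and beside a named gene only where it changed a call. For lists only a replicate block over all samples was fitted. The covariance that shared deviations within a treatment put into the 2 responses was taken off the covariance of the responses, a test chosen after seeing the data. Shared deviations between treatments enter with the opposite sign and were not counted. The jackknife SE of the predicted dilution in IgM+ libraries, also added then, and that of the correlation leave out 1 library at a time over all samples and not within groups, which makes them larger.

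Alternatives were a stricter threshold of 0.01, DESeq2 size factors (RLE), library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in at least 3 samples, a replicate block, a fit of only the 2 groups compared, no immunoglobulin genes, a tested minimum fold of 1.5 (glmTreat), limma on log2(TPM + 1) or log2(TPM + 0.1) at a mean TPM of at least 1 or unfiltered, and leaving out each sample. Fits on TPM are on the log2(TPM + pseudocount) scale, which understates the change of low genes. A further 4 were chosen after seeing the data, which were thinning all libraries to the shallowest, thinning the IgG1+ libraries to the IgM+ totals, blocking within treatment, and leaving out the 2 shallowest libraries.

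The tests were first run on simulated counts with the means and library sizes of these samples and 200 changed genes. The counts were drawn independently for each library, with 1 mean and 1 dispersion per gene. Deviations shared by replicate number and a larger spread in 1 isotype were thus left out, so the rates hold only for such counts. For the IgM+ response, simulated over 11713 genes, 55.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97% of those changed 4-fold were recovered. The corresponding shares were 61.2%, 94% and 98.5% for the IgG1+ response over 11715 genes, and 70.1%, 88.1% and 100% for the untreated isotypes over 11704. They were 68.7%, 89.6% and 98.5% for the anti-kappa isotypes over 11717 genes, and 32.8%, 73.1% and 93.9% for the difference of the responses over 11703. False calls were 3.70%, 3.98%, 4.97%, 6.04% and 4.32% of all calls in these 5 simulations, in the same order.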

Results

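RNA sequencing counts were obtained from 12 samples of mouse iGB-cultured B cells, in 4 groups of 3 that cross the surface isotype (IgM+ or IgG1+) with the treatment (untreated or anti-kappa for 12 h). Total counts of replicates 1, 2 and 3 were 2263801, 2119039 and 4632323 in untreated IgM+ cells, and 5428213, 5560646 and 6390017 in anti-kappa IgM+ cells. They were 7647553, 7130528 and 7705607 in untreated IgG1+ cells, and 6159982, 6919756 and 6283815 in anti-kappa IgG1+ cells. Replicates 1 and 2 of untreated IgM+ cells were thus the shallowest libraries. The first principal component of log2 CPM held 47.4% of the variance, and all 6 IgM+ libraries lay on the other side of 0 from all 6 IgG1+ libraries. Coordinates are those of mm10 in the deposited table, and errors of levels are SDs with n = 3. A signed or unsigned number after a gene with no unit is its log2 change in the comparison at hand.

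The isotype genes were read first, because they check the sort. The heavy chain constant gene Ighm (chromosome 12, 113418558 to 113422730) had 6282 ± 537 CPM in untreated and 5848 ± 132 CPM in anti-kappa IgM+ cells, against 191 ± 22 and 195 ± 24.4 CPM in IgG1+ cells. Ighg1 (chromosome 12, 113325240 to 113330523), the constant gene of the switched isotype, had 702 ± 36.4 and 739 ± 56.5 CPM in IgM+ cells, against 4057 ± 106 and 4689 ± 111 CPM in IgG1+ cells. The log2 ratio of Ighg1 to Ighm counts was 4.51 ± 0.20 (SD, n = 6) in IgG1+ and -3.07 ± 0.18 (SD, n = 6) in IgM+ libraries, a difference of 7.58 with an exact two-sided permutation p of 0.00216. The lowest IgG1+ library stood at 4.19 and the highest IgM+ library at -2.84, so every library matched its label. Within a treatment the exact test of 3 against 3 libraries cannot give a p under 0.1, and the differences were 7.57 untreated and 7.58 with anti-kappa. Ighd (chromosome 12, 113406604 to 113416324), which naive cells express with Ighm, had 175 ± 23.9 CPM in untreated IgM+ and 7.02 ± 0.534 CPM in untreated IgG1+ cells.

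**Figure D1:**
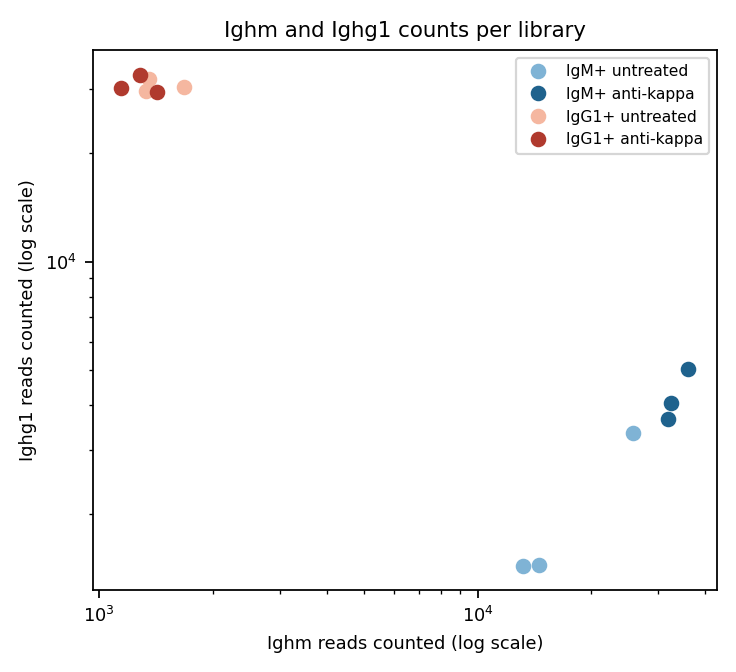
Counts of Ighm against Ighg1 in each of the 12 libraries, both axes logarithmic, with points coloured by group. The IgM+ libraries have more Ighm than Ighg1 counts and the IgG1+ libraries the reverse.

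The first comparison asked what differed between sorted IgM+ cells with and without anti-kappa, and few genes passed. Cells were sorted after the treatment, by the isotype that the antibody engages, by survival and by CD138. A change within cells therefore cannot be told apart from a change in which cells were sorted. The same limit holds for every comparison with anti-kappa cells. Fosb (chromosome 7, 19302696 to 19310051), an AP-1 transcription factor gene, fell from 102 ± 12.3 to 35.2 ± 12 CPM, 2.88-fold. Fos (chromosome 12, 85473890 to 85477273) fell from 95.8 ± 1.49 to 56 ± 4.01 CPM and Junb from 245 ± 15 to 186 ± 14.5 CPM. Csf1 (chromosome 3, 107741048 to 107760469), which encodes a myeloid growth factor, rose 1.6-fold from 26.9 ± 2.15 to 43.4 ± 4.09 CPM, and the pro-apoptotic gene Bmf rose 1.45-fold to 79.2 ± 2.95 CPM. In edgeR 42 genes passed, 16 higher and 26 lower, and 1115 had an unadjusted p under 0.05. The split was 19 higher and 8 lower with library totals alone, and 75% to 100% were higher with TPM. More genes passed with DESeq2 (111), with no low-count filter (137) and with a replicate block (285). Of the 42, 1 was at least 2-fold higher and 2 at least 2-fold lower. The count rested on single libraries: it was 1, 11 and 92 without untreated IgM+ replicate 1, 2 or 3, and 9, 3 and 11 without anti-kappa IgM+ replicate 1, 2 or 3. It was also 13 and 9 without anti-kappa IgG1+ replicate 1 or 2, and 7 without untreated IgG1+ replicate 1. Without the 2 shallowest libraries, which leaves 1 untreated IgM+ library with a spread taken from the other groups, 3 genes passed. Each of the 15 named genes that passed lost its call in at least 1 of the 12 leave-one-out fits, and 0 changed sign.

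Csf1 had a log2 fold change of 0.68 ± 0.11 (SE; adjusted p = 0.0129) and Bmf 0.54 ± 0.09 (adjusted p = 0.0136). Both lost the call without untreated IgM+ replicate 1 or anti-kappa IgM+ replicate 2, with adjusted p up to 0.0877 and 0.0958. Junb changed by -0.39 ± 0.07 (adjusted p = 0.0129), and lost the call without untreated IgM+ replicate 1 or anti-kappa IgM+ replicate 1 or 3, with adjusted p up to 0.0877. Fosb changed by -1.53 ± 0.21 and Fos by -0.77 ± 0.13 (adjusted p = 0.0375 for each), and they kept the call in 5 and 4 of the 12 fits, with adjusted p up to 0.123 and 0.135. The other risers were Enpp6 (1.06), Serinc5 (0.64), Klhdc2 (0.60), the survival kinase gene Pim2 (0.60) and the DNA glycosylase gene Neil1 (0.42). The other genes that fell were Avil (-1.36), Sh2d6 (-0.82), Cdh17 (-0.74), Ckb (-0.65) and the B cell scaffold gene Bank1 (-0.28). Among these, Serinc5 kept the call in 8 fits, Pim2 in 6, Neil1 in 5, Avil, Ckb and Bank1 in 4, Sh2d6 in 3, Enpp6 in 2, and Klhdc2 and Cdh17 in 1.

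Genes that drive plasma cell differentiation did not pass in IgM+ cells. Prdm1 (chromosome 10, 44437177 to 44528501), which encodes Blimp-1, changed by 0.01 on the log2 scale with a 95% interval of -0.46 to 0.48. Irf4 (chromosome 13, 30749226 to 30766976) changed by -0.03, with an interval of -0.19 to 0.14, and Egr2 (chromosome 10, 67535475 to 67542188), an early growth response factor gene, by -0.03, with an interval of -0.25 to 0.19. The pro-apoptotic Bcl2l11 (chromosome 2, 128126038 to 128162547), which encodes BIM, changed by 0.26 ± 0.10 (adjusted p = 0.354). Egr1 changed by -0.37 (adjusted p = 0.0785), Myc (chromosome 15, 61985391 to 61990374) by -0.29, Nr4a1 by 0.12, Mcl1 by -0.07, Bcl6 (chromosome 16, 23965052 to 23988852) by -0.04 and Bach2 (chromosome 4, 32238804 to 32586108) by 0.08. The light chain gene Igkc (chromosome 6, 70726435 to 70726966) changed by -0.14 and Ighm by -0.10.

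Among the lists in IgM+ cells, the immediate-early list was lower (15 tested, 0 higher, 3 lower, 12 not passed, 7 adjusted over the list alone), with a median log2 fold change of -0.29 (adjusted p = 5.5e-09, and adjusted p = 0.0136 with an estimated correlation, so the call held). The other lists that passed at the preset correlation had 0 members past the threshold over all genes. MYC targets and ribosome biogenesis were lower, with a median of -0.20 and 8 adjusted over the list alone (adjusted p = 1.93e-08, and adjusted p = 0.399 with an estimated correlation). MHC class II genes were lower, with a median of -0.10 and 6 adjusted over the list alone (adjusted p = 5.5e-09, and adjusted p = 0.315 with an estimated correlation). NF-kB targets had a median of -0.08 and 0 adjusted over the list alone (adjusted p = 0.0056, and adjusted p = 0.12 with an estimated correlation). Proximal BCR signalling had a median of -0.07 and 0 adjusted over the list alone (adjusted p = 0.00070, and adjusted p = 0.315 with an estimated correlation). Glycolysis genes were higher, with a median of 0.45 and 0 adjusted over the list alone (adjusted p = 1.97e-06, and adjusted p = 0.461 with an estimated correlation). With a replicate block 7 of these 19 genes passed over all genes, all of them higher. G2 and M phase genes were also higher, with a median of 0.12 and 0 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.397 with an estimated correlation). The other 22 lists with a set test did not pass in this comparison, among them the plasma cell program (adjusted p = 0.389) and ERK feedback (adjusted p = 0.488).

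The next comparison asked the same question in IgG1+ cells, where genes of plasma cell differentiation rose. Sdc1, the gene of CD138, rose too, although CD138+ cells were sorted out. In IgG1+ replicates 1, 2 and 3 it had 1.80, 1.24 and 1.29 CPM untreated, and 8.72, 7.17 and 10.5 CPM with anti-kappa. Prdm1 rose 4.8-fold, from 9.85 ± 0.951 to 47.5 ± 9.63 CPM. Irf4, which acts with it, rose 2.57-fold, from 78.3 ± 4.3 to 202 ± 16.3 CPM. Xbp1, which widens the secretory apparatus, rose 2.09-fold to 291 ± 30.3 CPM. Jchain, which joins antibody multimers, rose 2.48-fold to 616 ± 61.4 CPM. Bcl2l11 rose 3.88-fold, from 46 ± 1.14 to 179 ± 8.42 CPM. The costimulatory ligand gene Cd86 fell 2.53-fold, from 88.1 ± 1.09 to 34.9 ± 1.17 CPM. In edgeR 2473 genes passed, 1162 higher and 1311 lower, of which 159 were at least 2-fold higher and 173 at least 2-fold lower. The share of higher calls was 47.0%, against 34.5% to 35.8% with TPM. Of the 114 named genes that passed, 99 kept the call without any 1 library, 15 lost it at least once, and 0 changed sign.

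**Figure D2:**
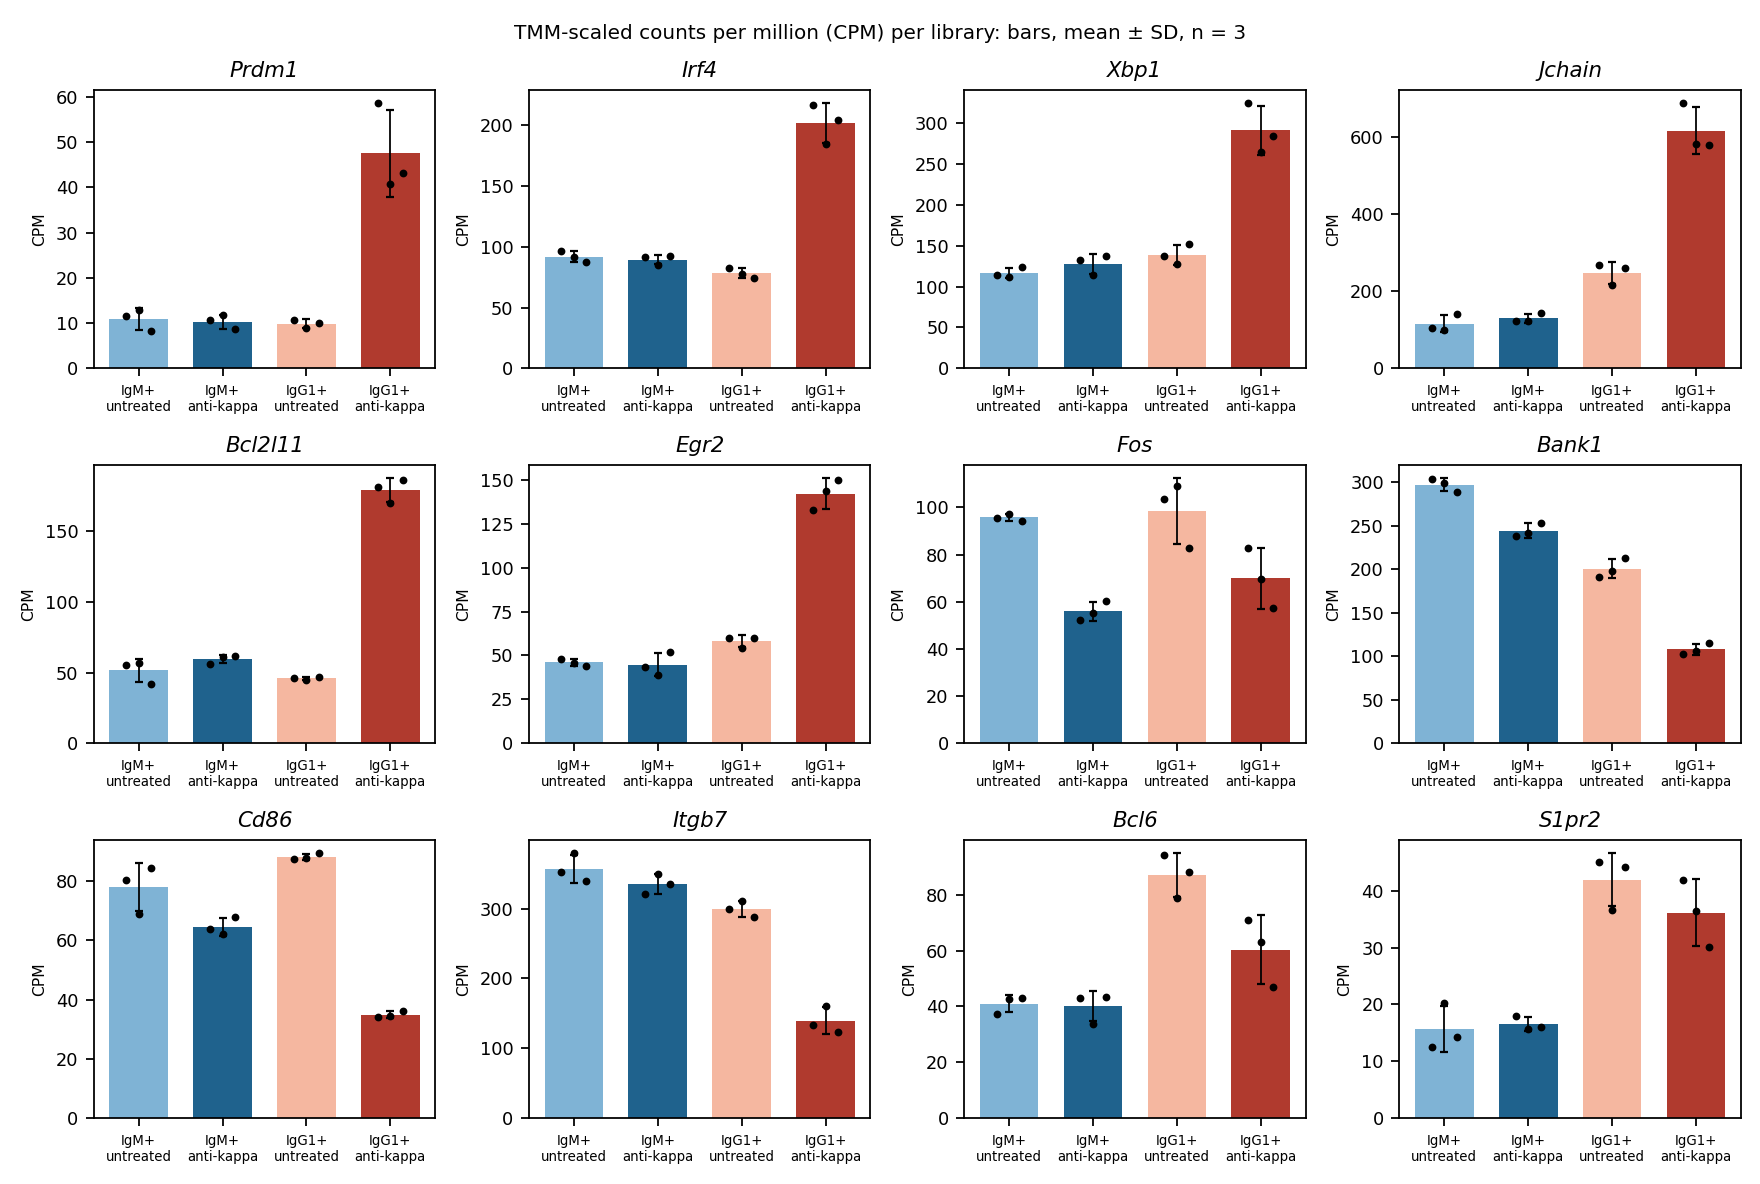
TMM-scaled CPM of 12 genes in the 4 groups; bars are means, error bars SDs, n = 3, and points libraries. Prdm1, Irf4 and Bcl2l11 are highest in anti-kappa IgG1+ cells.

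The log2 fold changes in IgG1+ cells were 2.26 ± 0.14 (SE) for Prdm1 (adjusted p = 4.38e-11), 1.36 ± 0.07 for Irf4 (adjusted p = 4.97e-13) and 1.96 ± 0.08 for Bcl2l11 (adjusted p = 3.18e-15). Large rises were in Il18rap (chromosome 1, 40515362 to 40551705) and Il18r1 (chromosome 1, 40465552 to 40500854), which encode the chains of the IL-18 receptor. Il18rap rose from 0.965 ± 0.194 to 9.35 ± 1.17 CPM (3.25 ± 0.29). Il18r1 rose from 1.46 ± 0.538 to 12.5 ± 2.38 CPM (3.09 ± 0.25). Enam (chromosome 5, 88487975 to 88506049) rose from 1.75 ± 0.717 to 15.7 ± 1.87 CPM. Gucy1b1 (chromosome 3, 82032006 to 82074689), a guanylate cyclase subunit gene, rose from 1.24 ± 0.359 to 9.92 ± 0.677 CPM, and Akap6 by 2.83 on the log2 scale. Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G protein signalling, rose 7.53-fold from 1.93 ± 0.13 to 14.6 ± 2.91 CPM. Large falls were in Avil (-2.72), Cdh17 (chromosome 4, 11758147 to 11817895; -2.26), Ppl (chromosome 16, 5086291 to 5132421; -2.25), Hbb-bh1 (-2.24), Alox5ap (-2.23) and Lrrc25 (-2.17).

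The plasma cell program was higher in anti-kappa IgG1+ cells (19 tested, 12 higher, 2 lower, 5 not passed, 16 adjusted over the list alone), with a median log2 fold change of 0.75 (adjusted p = 3.08e-09, and adjusted p = 0.053 with an estimated correlation). Trib1 in that list rose 4.81-fold. The unfolded protein response and secretion list was higher (25 tested, 16 higher, 1 lower, 8 not passed, 21 adjusted over the list alone), with a median of 0.28 (adjusted p = 2.76e-09, and adjusted p = 0.0809 with an estimated correlation). The chaperone gene Hsp90b1 changed by 0.75 ± 0.06, Edem1 by 0.54 and the stress sensor gene Ern1 by 0.97. Mature B cell identity genes were lower (24 tested, 1 higher, 15 lower, 8 not passed, 18 adjusted over the list alone), with a median of -0.33 (adjusted p = 3.08e-09, and adjusted p = 0.133 with an estimated correlation). They included Bank1 (-0.90), Ralgps2 (-0.63), Cd37 (-0.39) and Ms4a1 (-0.46), which encodes CD20. The memory B cell program was lower (19 tested, 0 higher, 13 lower, 6 not passed, 15 adjusted over the list alone), with a median of -0.63 (adjusted p = 3.08e-09, and adjusted p = 0.053 with an estimated correlation). Tle3 (-0.95), Ccr6 (-0.77), Vim (-0.65) and Hhex (-0.53) fell. The germinal centre program went both ways (20 tested, 8 higher, 5 lower, 7 not passed, 14 adjusted over the list alone), with a median of -0.03, a mean of 0.10 and a set test towards higher values that did not pass (adjusted p = 0.547). In it Rgs13 rose by 2.35, Stap1 by 0.50 and Pou2af1 by 0.29, while Lmo2 changed by -0.88 and Bcl6, a repressor of Prdm1, by -0.53 ± 0.12 (adjusted p = 0.0050).

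Genes of BCR signalling and antigen presentation were lower in anti-kappa IgG1+ cells. Proximal BCR signalling (26 tested, 2 higher, 15 lower, 9 not passed, 18 adjusted over the list alone) had a median of -0.22 (adjusted p = 3.17e-07, and adjusted p = 0.0481 with an estimated correlation, so the call held). Plcg2 (-0.48), Malt1 (-0.54) and Prkcb (-0.54) fell and Vav3 rose by 1.09. Inhibitory BCR regulators (23 tested, 2 higher, 12 lower, 9 not passed, 18 adjusted over the list alone) had a median of -0.26 (adjusted p = 1.19e-07, and adjusted p = 0.0809 with an estimated correlation). Pirb, an inhibitory receptor gene, stood at -1.51 ± 0.11, Lilrb4a at -1.27, the ubiquitin ligase gene Cblb at -1.03 and Pag1 at -0.51. MHC class II and antigen presentation (21 tested, 0 higher, 13 lower, 8 not passed, 16 adjusted over the list alone) had a median of -0.21 (adjusted p = 3.08e-09, and adjusted p = 0.144 with an estimated correlation). There the lysosomal reductase gene Ifi30 fell 2.11-fold to 188 ± 23 CPM, and H2-Oa (-0.50), H2-DMa (-0.43) and H2-DMb2 (-0.32) fell too. Integrins, adhesion and migration (16 tested, 0 higher, 10 lower, 6 not passed, 10 adjusted over the list alone) had a median of -0.24 (adjusted p = 6.18e-06, and adjusted p = 0.0133 with an estimated correlation, so the call held). Itgb7, which pairs with the product of Itga4, fell 2.14-fold from 299 ± 11.1 to 139.6 ± 19 CPM, Itga4 changed by -0.84 and the follicle-homing receptor gene Cxcr5 by -0.58. Interferon-stimulated genes (16 tested, 0 higher, 7 lower, 9 not passed, 7 adjusted over the list alone) had a median of -0.24 (adjusted p = 0.00316, and adjusted p = 0.394 with an estimated correlation). Oas3 stood at -1.36 and Irf7 at -0.84.

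Targets of BCR-driven transcription moved in both directions in IgG1+ cells. NF-kB targets (19 tested, 0 higher, 11 lower, 8 not passed, 12 adjusted over the list alone) had a median of -0.23 (adjusted p = 3.09e-06, and adjusted p = 0.0133 with an estimated correlation, so the call held). The cytokine genes Lta (-1.13), Ltb (-0.65) and Tnf (-0.95) and the regulator Nfkbid (-0.74) fell. In the immediate-early list (15 tested, 3 higher, 7 lower, 5 not passed, 12 adjusted over the list alone) Egr2 rose 2.45-fold to 142 ± 8.72 CPM, while Junb changed by -0.54 and Ier5 by -0.48, and the list did not pass (adjusted p = 0.0506). Egr1 (-0.19), Nr4a1 (0.08) and Bach2 (0.18) did not pass. Myc changed by -0.43 ± 0.11 (adjusted p = 0.00612; adjusted p = 0.0641 without untreated IgG1+ replicate 1). ERK feedback (12 tested, 6 higher, 1 lower, 5 not passed, 9 adjusted over the list alone; adjusted p = 0.0529) held rises of Spry2 (1.69), Etv4 (1.29), Dusp4 (1.09) and Etv5 (0.94). Activation surface markers (15 tested, 2 higher, 7 lower, 6 not passed, 9 adjusted over the list alone; adjusted p = 0.103) held Tfrc (0.66), the transferrin receptor gene, and Il2ra (1.92) among risers, and Cd86 (-1.34 ± 0.08) and Cd69 (-0.48) among genes that fell. Chemokines and cytokines (5 tested, 2 higher, 0 lower, 3 not passed, 3 adjusted over the list alone; adjusted p = 0.179) had a median of -0.09 and a mean of 0.14, and Ccl22, which attracts T cells, rose 2.65-fold to 111 ± 5.86 CPM. IL-4 and STAT6 targets (12 tested, 2 higher, 3 lower, 7 not passed, 5 adjusted over the list alone; adjusted p = 0.763) had a median of -0.14 and a mean of 0.05.

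Lists of growth and survival were compared in the same cells. S phase genes (22 tested, 6 higher, 0 lower, 16 not passed, 10 adjusted over the list alone) had a median of 0.20 (adjusted p = 5.64e-05, and adjusted p = 0.439 with an estimated correlation). Gins2 stood at 0.59 and Dhfr at 0.36. MYC targets (30 tested, 8 higher, 1 lower, 21 not passed, 9 adjusted over the list alone) had a median of 0.17 (adjusted p = 0.00115, and adjusted p = 0.492 with an estimated correlation). Hspd1 stood at 0.57, Npm1 at 0.35 and Tcof1 at -0.49. Cholesterol synthesis (21 tested, 4 higher, 0 lower, 17 not passed, 12 adjusted over the list alone) had a median of 0.23 (adjusted p = 0.00121, and adjusted p = 0.492 with an estimated correlation), and Lss rose by 0.87. Oxidative phosphorylation (23 tested, 3 higher, 0 lower, 20 not passed, 3 adjusted over the list alone) had a median of 0.10 (adjusted p = 0.0221, and adjusted p = 0.519 with an estimated correlation). Glycolysis did not pass (adjusted p = 0.0506), with a median of 0.36 and 16 of 19 estimates positive. With a replicate block the list passed, as given below, and 14 of its 19 genes passed, 12 of them higher, against 3 without the block. Also not passing were G2 and M phase (adjusted p = 0.394), the ATF4 stress response (adjusted p = 0.388), p53 targets (adjusted p = 0.288) and anti-apoptotic genes (adjusted p = 0.084). Among the members of these lists Asns rose by 0.91, Gadd45a by 0.58 and Pim2 by 0.63, while Hif1a changed by -0.41, Ddit4 by -0.49, the BAFF receptor gene Tnfrsf13c by -0.80, Pim3 by -0.57 and Mcl1 by -0.24. Pro-apoptotic genes (16 tested, 4 higher, 4 lower, 8 not passed, 8 adjusted over the list alone; adjusted p = 0.814) had a median of -0.14 and a mean of 0.08, with Casp3 (0.58) and Bmf (0.49) higher and Bid (-0.61) lower. Immunoglobulin constant genes (12 tested, 3 higher, 0 lower, 9 not passed, 4 adjusted over the list alone; adjusted p = 0.123) included small rises of Ighg1 (0.21 ± 0.05) and Igkc (0.23 ± 0.05).

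Of the lists of markers of other cells, the myeloid list was lower with anti-kappa in IgG1+ cells, and the T and NK cell list did not pass. The summed CPM of myeloid markers were 125 ± 3.33 untreated and 74.0 ± 3.56 with anti-kappa, with Mpeg1 at -1.31 and Itgam at -1.25 (6 tested, 0 higher, 4 lower, 2 not passed, 5 adjusted over the list alone; adjusted p = 0.000683, and adjusted p = 0.0481 with an estimated correlation, so the call held). Fibroblast feeder markers summed to 89.1 ± 12.0 and 46.3 ± 9.40 CPM (4 tested, 0 higher, 1 lower, 3 not passed, 2 adjusted over the list alone), with S100a6 at -1.74, and Col1a2 and Col3a1 had 0 counts in every library. T and NK cell markers summed to 187 ± 4.48 and 158 ± 11.6 CPM (6 tested, 2 higher, 1 lower, 3 not passed, 3 adjusted over the list alone; adjusted p = 0.604), with Cd2 at -0.98, Lck at 0.91, and Cd3e at 0 counts in every library. Erythroid and platelet markers summed to 3.82 ± 0.184 and 5.57 ± 0.351 CPM, and of 2 tested 0 passed.

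The isotypes were then compared in untreated cells, which asked how switched and unswitched cells differed before the antibody. Genes of the germinal centre program were among those that differed. S1pr2 (chromosome 9, 20962361 to 20976781), a receptor gene that keeps cells in follicles, was 2.74-fold higher, at 41.9 ± 4.64 against 15.6 ± 4.02 CPM. Bcl6, the germinal centre master regulator, was 2.11-fold higher, at 87.1 ± 7.76 against 41 ± 3.15 CPM. Cd38, whose surface product mouse germinal centre cells lose, was 2.05-fold lower, at 26.7 ± 4.12 against 55.3 ± 4.12 CPM. Bach2, which restrains plasma cell differentiation, was 1.49-fold lower, at 84.9 ± 9.35 against 127 ± 16.4 CPM. In edgeR 2359 genes passed, 1228 higher and 1131 lower in IgG1+ cells, of which 64 were at least 2-fold higher and 143 at least 2-fold lower. The share of higher calls was 52.1%, against 70.3% with library totals alone and 83.3% to 84.0% with TPM, where the median of all genes was 0.073 to 0.16. With RLE 1160 were higher and 1213 lower. With the replicate block within treatment 3251 genes passed, 1698 higher and 1553 lower. Without the 2 shallowest libraries 580 genes passed, 237 higher and 343 lower, but that fit has 1 untreated IgM+ library, whose spread is taken from the other groups. Of the 104 named genes that passed, 85 kept the call without any 1 library, 19 lost it at least once, and 0 changed sign.

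The log2 differences of IgG1+ minus untreated IgM+ cells were 2.53 ± 0.06 (SE) for Ighg1, -5.04 ± 0.11 for Ighm, -4.62 ± 0.12 for Ighd and -3.52 ± 0.41 for Ighg3, another heavy chain constant gene. The germinal centre list (20 tested, 13 higher, 1 lower, 6 not passed, 16 adjusted over the list alone) had a median of 0.31 (adjusted p = 7.76e-06, and adjusted p = 0.0635 with an estimated correlation). S1pr2 stood at 1.46 ± 0.16 (adjusted p = 6.51e-07), Bcl6 at 1.07 ± 0.15 (adjusted p = 0.000105), Nuggc at 1.5, Gcsam at 1.43 and Mef2b at 0.84. Slpi (1.4), Hbb-bh1 (1.7) and Jchain (1.07) were also higher, and Fcrl5 (-1.8), Csf2rb (-1.65) and Cacna1e (-1.62) lower. Irf4 did not pass (-0.22 ± 0.08, adjusted p = 0.0511), but did with the replicate block within treatment, chosen after the data were seen (adjusted p = 0.0085). Myc behaved alike (0.29 ± 0.12, adjusted p = 0.109; adjusted p = 0.0339 with that block). Prdm1 (-0.05) and Bcl2l11 (-0.11) did not pass. Egr1 and Egr2 passed (log2 differences of 0.31 and 0.34), but lost the call in 3 leave-one-out fits each. Without untreated IgM+ replicate 1 or 2 or untreated IgG1+ replicate 3 the adjusted p of Egr1 was up to 0.0811. Without untreated IgG1+ replicate 1 or 3 or untreated IgM+ replicate 3 that of Egr2 was up to 0.0827.

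Lists of proliferation and growth were higher in untreated IgG1+ cells. MYC targets and ribosome biogenesis (30 tested, 26 higher, 0 lower, 4 not passed, 28 adjusted over the list alone) had a median of 0.46 (adjusted p = 5.03e-16, and adjusted p = 0.0813 with an estimated correlation). Nop58 (0.68), Nolc1 (0.64), Hspd1 (0.64) and Mybbp1a (0.48) were higher. S phase genes (22 tested, 20 higher, 0 lower, 2 not passed, 22 adjusted over the list alone) had a median of 0.54 (adjusted p = 4.76e-16, and adjusted p = 0.0813 with an estimated correlation). Dhfr (0.68), Mcm4 (0.56), Rrm1 (0.47) and Rrm2 (0.44) were higher. G2 and M phase genes (24 tested, 19 higher, 0 lower, 5 not passed, 22 adjusted over the list alone) had a median of 0.32 (adjusted p = 2.57e-13, and adjusted p = 0.0813 with an estimated correlation). Aurkb (0.49), Cdk1 (0.47) and Top2a (0.33) were higher. Oxidative phosphorylation (median 0.14; adjusted p = 0.000901, and adjusted p = 0.402 with an estimated correlation), cholesterol synthesis (median 0.21; adjusted p = 0.000866, and adjusted p = 0.508 with an estimated correlation) and the unfolded protein response (median 0.19; adjusted p = 0.000567, and adjusted p = 0.191 with an estimated correlation) were higher. The ATF4 stress response (14 tested, 7 higher, 1 lower, 6 not passed, 9 adjusted over the list alone) passed with the replicate block over all samples but not without it (adjusted p = 0.0641, 0.0447 with the block, and adjusted p = 0.425 with an estimated correlation and no block), and Shmt2 (0.70) and Slc7a5 (0.72) were higher. Glycolysis likewise passed with that block alone (adjusted p = 0.138, 0.000165 with the block, and adjusted p = 0.674 with an estimated correlation and no block).

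Lists of mature B cells were lower in untreated IgG1+ cells. Mature B cell identity (24 tested, 0 higher, 19 lower, 5 not passed, 21 adjusted over the list alone) had a median of -0.35 (adjusted p = 3.95e-15, and adjusted p = 0.0813 with an estimated correlation). Cd79b (-0.60), Cd79a (-0.39), Bank1 (-0.56), Cd55 (-0.59), Cnr2 (-0.52) and Fcer2a (-0.36) were lower. MHC class II (21 tested, 0 higher, 17 lower, 4 not passed, 18 adjusted over the list alone) had a median of -0.33 (adjusted p = 2.57e-13, and adjusted p = 0.0813 with an estimated correlation). H2-Aa (-0.42), H2-Eb1 (-0.42) and their activator Ciita (-0.41) were lower. The memory program (median -0.27; adjusted p = 5.58e-05, and adjusted p = 0.0813 with an estimated correlation), proximal BCR signalling (median -0.10; adjusted p = 7.76e-06, and adjusted p = 0.0813 with an estimated correlation) and inhibitory BCR regulators (median -0.20; adjusted p = 2.09e-05, and adjusted p = 0.121 with an estimated correlation) were lower. Integrins were lower too (median -0.27; adjusted p = 0.000664, and adjusted p = 0.0635 with an estimated correlation), and Sell stood at -0.44 and Ccr7 at -0.46. Interferon-stimulated genes (median -0.30; adjusted p = 0.00193, and adjusted p = 0.396 with an estimated correlation) and NF-kB targets (median -0.14; adjusted p = 0.0113, and adjusted p = 0.0813 with an estimated correlation) were also lower. T and NK cell markers summed to 273 ± 16.4 CPM in IgM+ and 187 ± 4.48 CPM in IgG1+ untreated cells, with Cd2 at -0.81. Most of both sums was Cd2, at 228 ± 17.4 and 130 ± 2.66 CPM, so they do not measure the number of T and NK cells.

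Compared after anti-kappa, the isotypes differed in more genes, and plasma cell genes were among them. Prdm1 was 4.61-fold higher in IgG1+ cells, at 47.5 ± 9.63 against 10.3 ± 1.52 CPM. Irf4 was 2.25-fold higher, at 202 ± 16.3 against 89.6 ± 4.0 CPM, and Jchain 4.74-fold, at 616 ± 61.4 against 129.7 ± 12 CPM. Bcl2l11 was 3.0-fold higher, at 179 ± 8.42 against 59.6 ± 3.08 CPM. Itgb7 was 2.4-fold lower in IgG1+ cells, at 139.6 ± 19 against 336 ± 14.4 CPM. The neonatal Fc receptor gene Fcgrt stood at 17.9 ± 3.8 against 82.1 ± 11.6 CPM. In edgeR 5469 genes passed, 2751 higher and 2718 lower, of which 317 were at least 2-fold higher and 421 at least 2-fold lower. The share of higher calls was 50.3%, against 60.8% to 61.9% with TPM. With the replicate block within treatment 6173 genes passed, 3074 higher and 3099 lower. Of the 123 named genes that passed, 119 kept the call without any 1 library, 4 lost it at least once, and 0 changed sign.

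The log2 differences of IgG1+ minus anti-kappa IgM+ cells were 2.21 ± 0.15 (SE; adjusted p = 6.93e-11) for Prdm1, 1.17 ± 0.07 (adjusted p = 2.3e-12) for Irf4 and 1.58 ± 0.08 (adjusted p = 1.04e-13) for Bcl2l11. Enam had 0.22 ± 0.239 CPM in IgM+ and 15.7 ± 1.87 CPM in IgG1+ cells, and Gucy1b1 had 0.536 ± 0.214 and 9.92 ± 0.677 CPM. Rgs13 (3.51), Trib1 (2.54), Spry2 (2.01), Ccl22 (1.76), Egr2 (1.66), Mef2b (1.5) and Ung (1.24), which excises uracil during switching, were higher. Csf2rb (-2.52), Ppl (-2.39), Adgre1 (-2.03), Mpeg1 (-1.86), Cd2 (-1.75), Cd38 (-1.62) and Pirb (-1.43) were lower. Markers of other cells summed to 103 ± 4.2 CPM in IgM+ and 74.0 ± 3.56 CPM in IgG1+ cells for myeloid cells, 284 ± 8.82 and 158 ± 11.6 CPM for T and NK cells, and 74.8 ± 13.2 and 46.3 ± 9.40 CPM for feeders. Igkc (-0.04) and Myc (0.16) did not pass.

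Of the lists after anti-kappa, MYC targets (30 tested, 29 higher, 0 lower, 1 not passed, 29 adjusted over the list alone) had a median of 0.87 (adjusted p = 4.73e-16, and adjusted p = 0.132 with an estimated correlation). Hspd1 stood at 1.34 and Nop58 at 1.15. S phase genes (22 tested, 22 higher, 0 lower, 0 not passed, 22 adjusted over the list alone) had a median of 0.80 (adjusted p = 1.71e-13, and adjusted p = 0.15 with an estimated correlation). The plasma cell program (19 tested, 11 higher, 3 lower, 5 not passed, 15 adjusted over the list alone) had a median of 0.93 (adjusted p = 8.25e-05, and adjusted p = 0.144 with an estimated correlation). The unfolded protein response (25 tested, 22 higher, 1 lower, 2 not passed, 24 adjusted over the list alone) had a median of 0.51 (adjusted p = 5.18e-10, and adjusted p = 0.0905 with an estimated correlation). Xbp1 stood at 1.18 and Hsp90b1 at 0.97. Cholesterol synthesis was higher (median 0.56; adjusted p = 9.85e-07, and adjusted p = 0.285 with an estimated correlation), and Idi1 stood at 1.1. G2 and M phase (median 0.23; adjusted p = 6.74e-05, and adjusted p = 0.285 with an estimated correlation) and the germinal centre program (median 0.34; adjusted p = 0.0106, and adjusted p = 0.133 with an estimated correlation) were also higher. Mature B cell identity (24 tested, 0 higher, 22 lower, 2 not passed, 23 adjusted over the list alone) had a median of -0.57 (adjusted p = 5.6e-14, and adjusted p = 0.0905 with an estimated correlation). The memory program (19 tested, 1 higher, 14 lower, 4 not passed, 17 adjusted over the list alone) had a median of -0.93 (adjusted p = 3.45e-07, and adjusted p = 0.0905 with an estimated correlation), and its member Ccr6 stood at -1.11. Integrins (16 tested, 2 higher, 10 lower, 4 not passed, 13 adjusted over the list alone) had a median of -0.75 (adjusted p = 0.00014, and adjusted p = 0.0403 with an estimated correlation, so the call held). NF-kB targets (19 tested, 1 higher, 12 lower, 6 not passed, 13 adjusted over the list alone), of which Ltb stood at -0.92, had a median of -0.41 (adjusted p = 0.000185, and adjusted p = 0.0403 with an estimated correlation, so the call held). MHC class II (median -0.41; adjusted p = 6.69e-10, and adjusted p = 0.133 with an estimated correlation), inhibitory BCR regulators (median -0.45; adjusted p = 4.98e-08, and adjusted p = 0.0905 with an estimated correlation) and interferon-stimulated genes (median -0.83; adjusted p = 0.000185, and adjusted p = 0.247 with an estimated correlation) were lower.

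The last comparison asked whether the response to anti-kappa differed between the isotypes, by testing the difference of the log2 fold changes, IgG1+ minus IgM+. For Prdm1 the difference was 2.25 ± 0.28 (SE; adjusted p = 1.87e-05), with 10.8 ± 2.4 and 10.3 ± 1.52 CPM in untreated and anti-kappa IgM+ cells. For Irf4 it was 1.39 ± 0.11 (adjusted p = 5.8e-09), for Bcl2l11 1.7 ± 0.13 (adjusted p = 5.8e-09) and for Egr2 1.32 ± 0.13 (adjusted p = 5.75e-07). The signalling regulator Rgs2 differed by 1.95 ± 0.16, standing at 177 ± 10.4 CPM in anti-kappa IgG1+ and 42.9 ± 7.06 CPM in anti-kappa IgM+ cells. Cd86 differed by -1.05 ± 0.11 (adjusted p = 1.07e-06) and Itgb7 by -1.01 ± 0.10 (adjusted p = 8.37e-07). In edgeR 673 genes passed, 269 higher and 404 lower, of which 46 were at least 2-fold higher and 63 at least 2-fold lower. Their count was 402 without anti-kappa IgM+ replicate 2, 433 without untreated IgM+ replicate 3, and 1524 with the replicate block within treatment. The share of higher calls was 40.0%, against 17.2% to 20.1% with TPM. Of the 673, 618 were also called in the IgG1+ response, which shares its libraries, and 19 in the IgM+ response. The estimated change was larger in IgG1+ than in IgM+ cells for 608, and the estimates had opposite signs for 349, although 0 were called in both responses with opposite signs. Of the 75 named genes that passed, 49 kept the call without any 1 library and 0 changed sign.

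**Figure D3:**
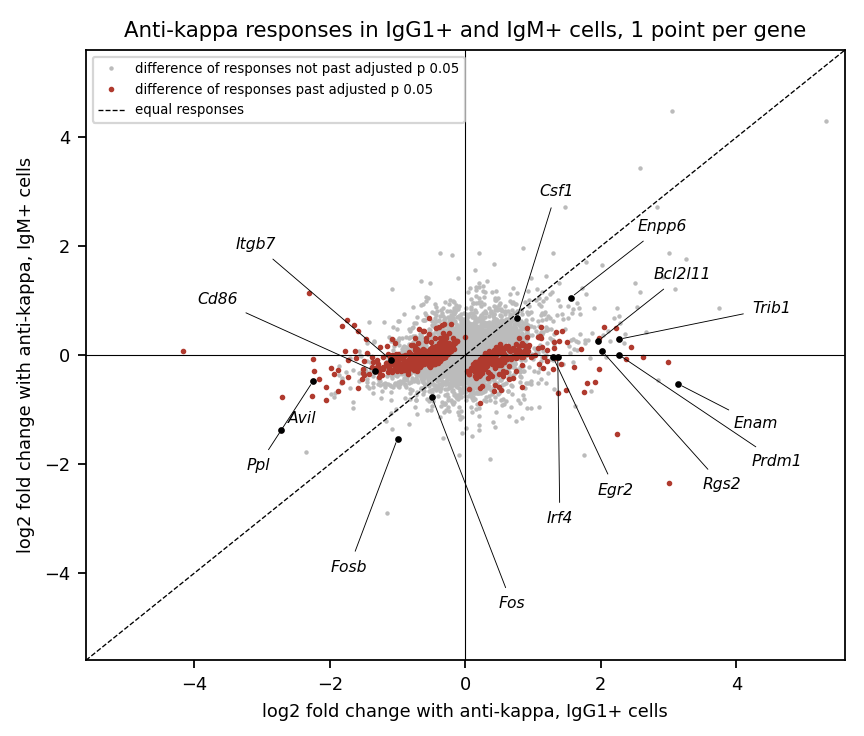
Log2 fold change with anti-kappa in IgG1+ cells (horizontal) against IgM+ cells (vertical), 1 point per gene, with equal responses on the dashed line. Red points are the 673 genes whose responses differed at an adjusted p under 0.05, and most lie farther from 0 horizontally than vertically.

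Further genes with a larger rise in IgG1+ cells were Rbm47 (2.45), Tacc2 (2.29), Ccl22 (1.56), Vav3 (1.25), Xbp1 (0.94) and Hsp90b1 (0.80). Trib1 (1.97) and Znrf3 (2.11) also passed, but had adjusted p of 0.0839 without untreated IgM+ replicate 3 and 0.0608 without untreated IgM+ replicate 2. Genes with a negative difference included Hbb-bh1 (-2.17), Tmem51 (-2.04), Alox5ap (-1.94), Ppl (-1.77), Gamt (-1.75), Lrrc25 (-1.74), Pirb (-1.18), Cd2 (-0.95), Lta (-0.82) and Ifi30 (-0.77). The plasma cell program (19 tested, 9 higher, 0 lower, 10 not passed, 11 adjusted over the list alone) had a median difference of 0.72 (adjusted p = 3.7e-09, and adjusted p = 0.0712 with an estimated correlation). The median difference was 0.35 in the unfolded protein response (25 tested, 11 higher, 1 lower, 13 not passed, 20 adjusted over the list alone; adjusted p = 5.41e-12, and adjusted p = 0.0712 with an estimated correlation). It was 0.39 in MYC targets (30 tested, 8 higher, 0 lower, 22 not passed, 20 adjusted over the list alone; adjusted p = 4.26e-10, and adjusted p = 0.248 with an estimated correlation). Mature B cell identity (24 tested, 0 higher, 6 lower, 18 not passed, 14 adjusted over the list alone) had a median difference of -0.23 (adjusted p = 2.1e-09, and adjusted p = 0.111 with an estimated correlation). The memory program (19 tested, 0 higher, 8 lower, 11 not passed, 10 adjusted over the list alone) had one of -0.59 (adjusted p = 7.25e-09, and adjusted p = 0.0712 with an estimated correlation). Integrins (16 tested, 0 higher, 6 lower, 10 not passed, 8 adjusted over the list alone) had a median difference of -0.32 (adjusted p = 6.99e-06, and adjusted p = 0.0258 with an estimated correlation, so the call held).

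**Figure D4:**
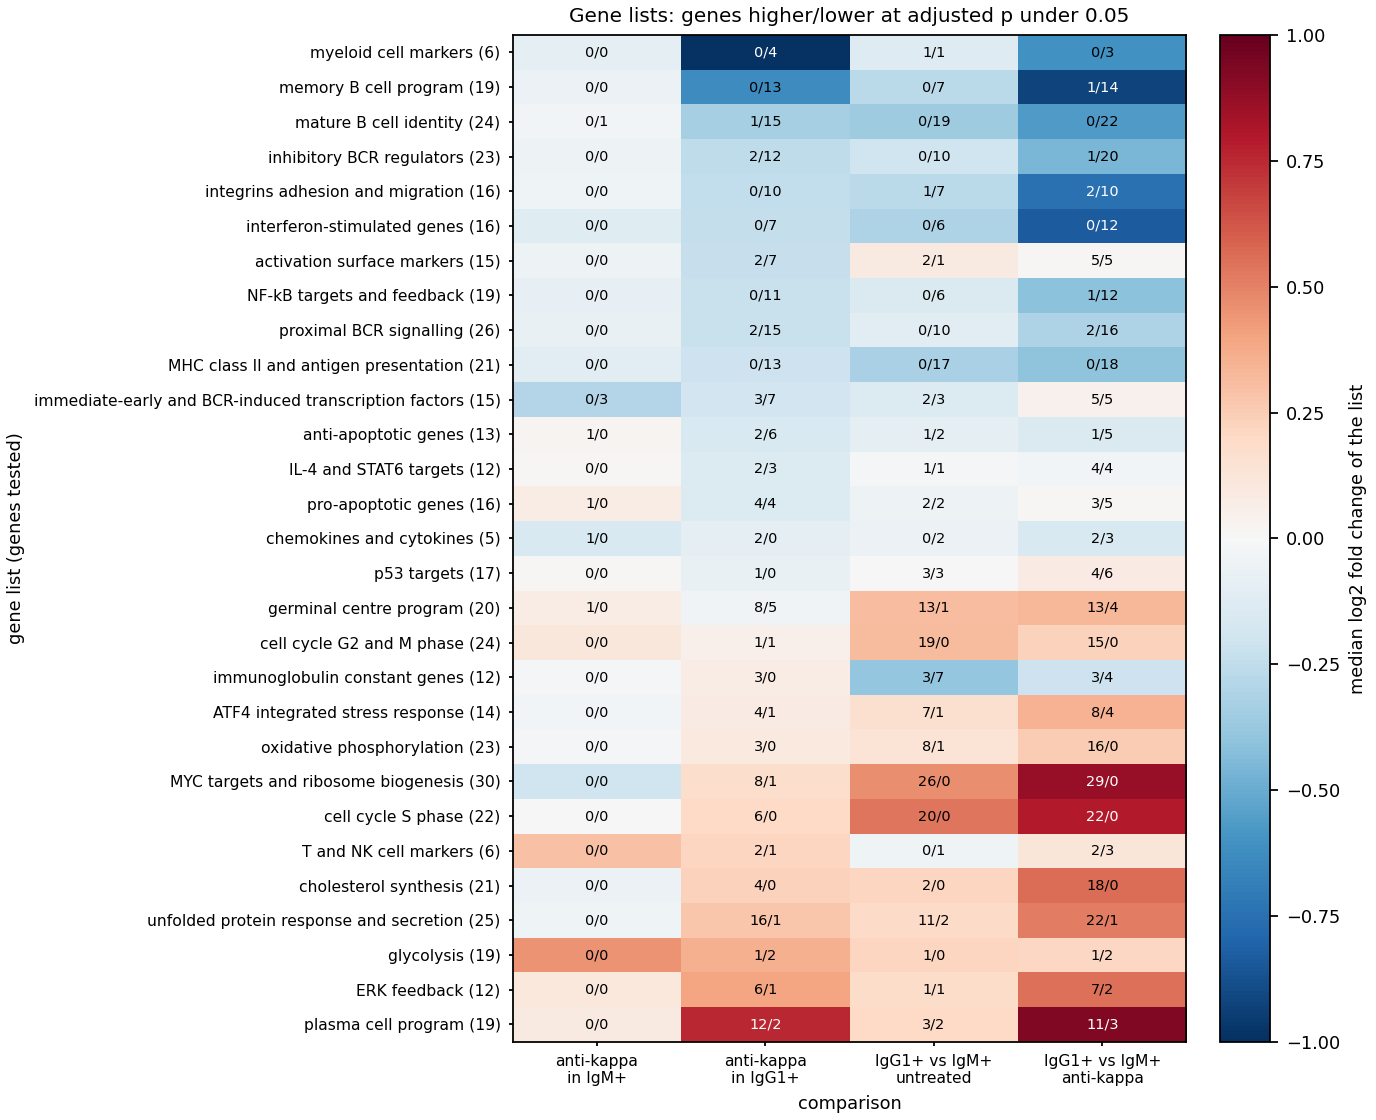
Numbers of members higher and lower in 29 gene lists (rows) and 4 comparisons (columns), with colour for the median log2 fold change from -1 to 1. The plasma cell list is higher, and the memory list lower, in anti-kappa IgG1+ cells than in untreated IgG1+ or anti-kappa IgM+ cells. With an estimated correlation none of these calls held (adjusted p = 0.053 for both against untreated, 0.144 and 0.0905 against IgM+ cells).

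The responses of the isotypes, which share no library, were correlated across 11875 genes with Pearson's r = 0.288 (jackknife SE 0.101) and Spearman's rho = 0.210, although genes are not independent replicates. Without the 2 shallowest libraries, with 1 untreated IgM+ library left, r was 0.158. Libraries with the same number deviated together within a treatment, which adds to r even with no response. On log2 CPM the covariance of the responses was 0.0271, of which such deviations gave 0.00628, and removing it took r from 0.292 to 0.224. Same-number libraries of different isotype and treatment also deviated together, with correlations of 0.00926 to 0.234, which lowers r. That part was not put back, so 0.224 takes off too much, by an amount not computed. A slope of IgM+ on IgG1+ responses corrected for noise was 0.249 (SE 0.174), and 0.4 without untreated IgM+ replicate 3. Of the 42 genes called in IgM+ cells, 14 were called higher and 13 lower in both isotypes, against 1.57 and 2.87 for independent lists, which leave those shared deviations out, and 0 were called in opposite directions. Csf1, Bmf, Pim2, Junb, Bank1 and Cdh17 were among those called in both. IgG1+ cells in the IgM+ sort, which are taken up below and not excluded, would also raise r, the slope and the shared calls.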

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

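The subset of 44 genes, the 16 lists and the 2 tests on the ratio of Ighg1 were chosen only after the results were seen; the tests of depth, of spread and of the diluted response were written before, though fits on thinned counts had by then been seen.

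The response to anti-kappa differed between the isotypes in 673 genes by the test of the difference, and the genes and lists below were picked out because that test passed for them. Plasma cell regulators and their companions responded more positively in IgG1+ cells, with differences of the log2 fold changes (IgG1+ minus IgM+) of 2.25 for Prdm1, 1.39 for Irf4, 0.94 for Xbp1, 0.80 for Hsp90b1 and 1.97 for Trib1. Signalling and survival genes with a positive difference were Egr2 (1.32), Bcl2l11 (1.7), Rgs2 (1.95), Vav3 (1.25), Ccl22 (1.56), Gadd45a (0.56) and Znrf3 (2.11). Rbm47 (2.45), Tacc2 (2.29), Hspd1 (0.70), Nop58 (0.47), Atp5b (0.30) and Igkc (0.37) were positive too. Nop58 lost the call without anti-kappa IgM+ replicate 2, anti-kappa IgG1+ replicate 3 or untreated IgM+ replicate 3 (adjusted p up to 0.112). Atp5b and Gadd45a kept it in 4 and 5 of the 12 leave-one-out fits, with adjusted p up to 0.16 and 0.145. Trib1 lost it without untreated IgM+ replicate 3 (adjusted p = 0.0839) and Znrf3 without untreated IgM+ replicate 2 (adjusted p = 0.0608).

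Genes picked out with a negative difference came from several lists and included Cd86 (-1.05), Itgb7 (-1.01), Bank1 (-0.62), Ralgps2 (-0.53), Ccr6 (-0.71), Vim (-0.66), Lmo2 (-0.77), Tnfrsf13c (-0.56), Prkcb (-0.51), Pag1 (-0.48) and Pirb (-1.18). Lta (-0.82), Ltb (-0.56), Ifi30 (-0.77), H2-DMa (-0.34) and Ddit4 (-0.62) were negative as well, and so was Pfkfb3 (-0.54), which kept the call in 4 of 12 leave-one-out fits, with adjusted p up to 0.09. Among the named genes, the largest negative differences were in Hbb-bh1 (-2.17), Tmem51 (-2.04), Alox5ap (-1.94), Ppl (-1.77), Gamt (-1.75) and Lrrc25 (-1.74). Markers on the lists of other cells differed too, with S100a6 at -1.33, Cd2 at -0.95 and Mpeg1 at -1.22.

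Median differences of the lists whose set test passed were 0.72 for the plasma cell program, 0.39 for MYC targets, 0.35 for the unfolded protein response, 0.33 for cholesterol synthesis, 0.23 for S phase and 0.13 for oxidative phosphorylation. They were -0.59 for the memory program, -0.74 for myeloid markers, -0.32 for integrins, -0.28 for interferon-stimulated genes, -0.25 for inhibitory BCR regulators and -0.23 for mature B cell identity. They were -0.16 for NF-kB targets, -0.14 for proximal BCR signalling, -0.10 for MHC class II and -0.063 for anti-apoptotic genes. With an estimated correlation, of these only integrins passed (adjusted p = 0.0258).

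More genes passed for anti-kappa in IgG1+ cells (2473) than in IgM+ cells (42), and the IgM+ libraries were shallower. With a replicate block the counts were 3381 and 285, a smaller gap in proportion, and the tests of depth and spread were run without that block. After the IgG1+ libraries were thinned to the totals of the IgM+ libraries, 1848 genes still passed, which argues against depth as the whole cause. When the IgG1+ fold changes were set over the SEs of the 6 IgM+ libraries, 1550 genes passed, against 13 of 11116 for the IgM+ fold changes, which argues against their larger spread (median SE 0.124 against 0.0996). The test of the difference of the responses passed for 673 genes. Why they differed stays open as untested, for example through a different binding of the antibody or a change in which cells were sorted. With 10 splits of 6 libraries a share under 0.05 cannot be reached; 1 split, the real one, gave as many genes in each isotype (2473 and 42, the highest other 0).

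The comparisons of the isotypes gave 2359 genes untreated and 5469 with anti-kappa, where again 1 of 10 splits gave as many, the highest other was 0, and the splits are too few for a share under 0.05. For the difference of the responses, 6 of 100 splits drawn gave at least 673 genes, the highest other 1570, so chance cannot be excluded by this count. In the split with 1570 the IgG1+ labels were reversed against those of the IgM+ libraries. The other splits as large kept the real grouping of the IgG1+ libraries, so the splits carry the real IgG1+ response.

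Ighg1 counts stood in the IgM+ libraries, at 17.3% (95% interval 16.0% to 18.8%) of the IgG1+ level untreated and 15.8% (14.5% to 17.1%) with anti-kappa. IgG1+ cells in the IgM+ sort may explain them, in which case no gene could have a lower IgM+ to IgG1+ ratio than Ighg1. Among genes with at least 5 CPM in IgG1+ cells, the number below that ratio at an adjusted p under 0.05 was 0 of 9713 untreated and 2 of 9748 with anti-kappa, Enam and Gucy1a1, which are near the floor in IgM+ cells. Untreated, 0 estimates lay below it and 0 genes lay close above it, so the untreated count could not decide. With anti-kappa 15 estimates lay below it, among them Gucy1b1 (5.5%), Rgs13 (8.78%) and Tacc2 (8.97%). Admixed cells would also give the IgM+ libraries a diluted IgG1+ response: over the 75 genes with a mean of at least 5 CPM in IgG1+ cells that rose at least 2-fold there, the median IgM+ log2 fold change was 0.28, against 0.37 predicted (difference -0.09, jackknife SE over libraries 0.09). Gene by gene, 48 lay below the prediction, with a median difference of -0.23 (jackknife SE 0.08), which runs against admixed cells as the only source; the test as written compared medians, but its code did so only after the output was first seen. The prediction takes IgM+ cells themselves as unmoved, so a fall of these genes in IgM+ cells would also lower it. Admixed cells therefore cannot be told apart from transcripts that IgM+ cells make from an unswitched Ighg1 locus, a biological explanation that was not tested.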

How the results depend on the processing

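Thinning, the replicate block within treatment and leaving out the 2 shallowest libraries were chosen only after the results were seen; the other alternatives were planned. No named gene or list was called with the opposite sign, but the balance of higher and lower calls turned in several fits, of which these are examples. The IgM+ response went from 16 higher and 26 lower to 19 and 8 with library totals alone, the IgG1+ response from 1162 and 1311 to 1259 and 1243. The untreated isotypes went from 1228 and 1131 to 1160 and 1213 with RLE, 854 and 891 when thinned, and 237 and 343 without the 2 shallowest libraries. The 42 genes of the IgM+ response were 2 at an adjusted p under 0.01, 27 with library totals alone, 111 with DESeq2, 24 with limma-voom, 137 with no filter, 13 with only the 2 groups compared, 0 with glmTreat (1115 at an unadjusted p under 0.05 in edgeR) and 16, 20 and 7 with TPM. They ranged from 1 to 92 without 1 library, and were 3 without the 2 shallowest, a fit with 1 untreated IgM+ library whose spread is taken from the other groups. Their share of higher calls was 38.1%, against 26.8% with RLE, 70.4% with library totals and 75% to 100% with TPM. The 2473 genes of the IgG1+ response were 1540 at 0.01, 228 with glmTreat, 1463, 1437 and 1192 with TPM, 1441 when all libraries were thinned, and 1806 to 2652 without 1 library. The 2359 genes of the untreated isotypes were 1342 at 0.01, 59 with glmTreat, 580 without the 2 shallowest libraries and 1602 to 2451 without 1 library. The 5469 of the anti-kappa isotypes were 756 with glmTreat and 4590 to 5598 without 1 library. The 673 of the difference of the responses were 293 at 0.01, 39 with glmTreat, 352 with unfiltered TPM, 378 when thinned and 402 to 748 without 1 library. The correlation of the responses was 0.288, with 0.194 to 0.307 without 1 library and 0.158 without the 2 shallowest. Of 145 list tests 71 passed, and 8 with an estimated correlation, 0 of them towards higher values. A stricter threshold and a tested minimum fold lower these counts by construction; for the others the cause was not tested. Replicate numbers did not pair samples across treatments by the criterion used. Still, within an isotype every sample correlated best with its own number, a hint from the data. With a replicate block 285 genes passed in IgM+ and 3381 in IgG1+ cells, and 1377 for the difference of the responses, 1524 with the replicate block within treatment. With the replicate block, lists gained a call for glycolysis (adjusted p = 4.41e-07) and immediate-early genes (0.0219) in the IgG1+ response, and for the memory program (0.0232) and inhibitory BCR regulators (0.028) in the IgM+ response; without the block and with an estimated correlation their adjusted p were 0.648, 0.193, 0.566 and 0.603. The replicate block within treatment was fitted for genes only. Besides the isotype results given with it in the report, it added calls in the difference of the responses for Gins2, Idi1, Insig1, Mcl1 and Mcm6. It changed no other call of the named genes of the isotype comparisons. With all libraries thinned to the shallowest, 10217 genes were tested and the IgM+ response had 43. The counts of the IgG1+ response and of the difference fell as given, so they were lower at that depth.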

Other observations

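The tests of the order of glycolysis genes by replicate number and the set of 85 ribosomal protein genes were chosen only after the data were seen.

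Genes of cytosolic ribosomal proteins, which were on no list, were lower in untreated IgG1+ than in untreated IgM+ cells. Of 85 tested, 74 were lower and 0 higher, with a median log2 difference of -0.45 (-0.46 with RLE, -0.38 with library totals alone). Without the 2 shallowest libraries 67 were lower and the median was -0.35, in a fit with 1 untreated IgM+ library whose spread is taken from the other groups. After anti-kappa 62 were lower and 2 higher, with a median of -0.24. In IgM+ cells the median change with anti-kappa was -0.21, with 9 lower and 0 higher, but -0.11 with 0 lower in that fit, and in IgG1+ cells it was 0.03. Their set test against other genes gave p = 2.51e-53 for the untreated isotypes, and p = 0.0161 with an estimated correlation. For the anti-kappa isotypes the same set test gave p = 1.71e-10, but p = 0.267 with an estimated correlation. Ribosomal protein genes took 6.77% ± 0.44 of the counts in untreated IgM+ and 5.25% ± 0.24 in untreated IgG1+ libraries (SD, n = 3 each), and the cause was not tested.

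Glycolysis genes stood in the same order of replicate numbers in all 4 groups, replicate 3 highest and replicate 1 lowest, with ranges of 0.70, 0.77, 0.61 and 0.65 on the log2 scale within a group. A state shared by libraries of 1 number, such as a culture or a processing day, may have set them. An exact two-sided permutation test of the order gave p = 0.00463, the smallest it can give, and 0.0224 adjusted over the 29 lists tried, of which 6 reached that p. The same exact permutation test on total counts gave p = 0.273, which cannot exclude library size. Replicate 3 also had the highest total in untreated IgM+, anti-kappa IgM+ and untreated IgG1+ cells, though not in anti-kappa IgG1+ cells. The labels name no batch, so a shared culture and a shared processing day stay open, as untested.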
